A study of Homo sapiens with 3 samples.

How the data were processed

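RNA from HCT116 cells was measured on 3 single-colour Affymetrix arrays of biotin-labelled cRNA: 1 with a scrambled hairpin as control and 1 each with UHRF1 hairpin 2 and hairpin 5. The deposited table holds log2 values that the authors made with Affymetrix Expression Console and RMA, per the submitters' processing notes. The notes used here give no versions or settings for either. The log base was inferred from the range of the values, from 1.95 to 14.06 on the control array, and the centring is not stated. The values carry no detection calls, so a level near the bulk of an array (25th percentile 2.57 on the control array) may be background, and folds against such a level are uncertain. Affymetrix control probe sets were not used here.

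Probe sets were named through the array platform's gene annotation. Of 54613 probe sets, 41091 had 1 gene, 1801 had several and 11721 were unnamed. Symbols were checked through gene identifiers in a RefSeq table of assembly GRCh38.p14, which matched 41037 of the named probe sets. The match changed the symbol of 0 probe sets, and 54 without a match kept the annotation's own symbol. That table was used for names only, and no coordinates are given. Each of 19775 genes was represented by its probe set with the highest mean over the arrays; 10523 genes had several. Genes with a mean at or above the 40th percentile (log2 3.28) were tested, 11865 in all.

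The hairpins share a source label and were treated as 2 replicates of UHRF1 depletion against 1 control array. The 2 arrays of the depleted group carry different hairpins, and no hairpin has a second array. The p-values of single genes therefore measure the spread between 2 hairpins, in which effects of the hairpin, the culture and the array cannot be separated. The fit was lmFit and eBayes in limma 3.58.1 (R 4.3.3), two-sided, with Benjamini-Hochberg adjustment over all genes tested. It has 1 residual degree of freedom per gene, moderated to 5.77, and assumes that the lone control varies like the hairpin arrays. An exact permutation over the 3 possible splits cannot go below p = 0.333. The same fit was tested on simulated data with 200 changed genes and on a simulated shift of a gene list by −1, which camera called.

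Because a single control gives no replicate check, genes at least 2-fold from the control in the same direction with both hairpins were also counted. Counts and correlations were set beside 100 draws of unchanged arrays sharing 1 control, with noise taken from the differences between hairpins by intensity bin, which also hold effects particular to 1 hairpin. Genes that differed 2-fold between the hairpins were counted without a test.

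Gene lists were written before the data were examined, as were the groups, the tests, the rule for named genes and most alternatives. The 30 lists were DNA methylation machinery, cancer-testis and germline genes, genes reported as promoter-methylated in colorectal cancer, p53 targets, S phase, G2 and mitosis, homologous recombination, histone genes, interferon-stimulated genes, antigen presentation, NF-kB and inflammatory genes, ATF4 and amino acid response, unfolded protein response, immediate early and AP-1 genes, Wnt targets, enterocyte and goblet genes, epithelial junction and keratin genes, mesenchymal and TGF-beta genes, cholesterol synthesis, glycolysis and hypoxia, oxidative phosphorylation, ribosomal proteins, metallothionein and NRF2 targets, imprinted genes, Polycomb and H3K9 methylation machinery, apoptosis regulators, senescence-linked secreted factors, and markers of leukocytes, of fibroblasts and endothelium, and of neurons. Lists with at least 5 tested genes were tested with camera in limma at its preset correlation of 0.01, two-sided, adjusted over the lists. At that preset the p-values take genes as their units and hold no spread between cultures, so they describe these arrays. List medians were placed among 10000 random lists of the same size matched on mean expression in 20 bins, as a description of these arrays. The limma p-values of members were also adjusted within each list alone, with no correction for the 30 lists.

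The named genes were UHRF1, the 12 higher and 12 lower genes with the largest smaller difference of the 2 hairpins, up to 4 members of each list by the same measure in the direction of the list's median, the 5 genes at each end of the difference between hairpins, and DNMT1, DNMT3A, DNMT3B, UHRF2, CDKN1A and CDKN2A. The member of each list furthest against its median, and NDRG4, GDF15, LIF, SOD2 and ISG20, were added after their values were seen. Probe sets of a gene were said to disagree where the mean difference reached 0.5 on both sides of 0, and no named gene met this.

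Alternatives were no expression filter, a filter at the 60th percentile, the mean of a gene's probe sets, no probe sets whose name ends in _x_at, median centring, cyclic loess, eBayes with an intensity trend or robust, an adjusted p of 0.1, all probe sets, 1.5-fold and 3-fold thresholds, each hairpin left out, and camera with an estimated correlation or on ranks. Counts without the interferon list were added after the data were examined. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.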

Results

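Gene expression was profiled on 3 Affymetrix arrays of HCT116, a human colorectal carcinoma cell line. The cells carried a scrambled short hairpin RNA (1 array) or one of a pair of hairpins against UHRF1, named hairpin 2 and hairpin 5 (1 array each), delivered by lentivirus, and were collected after 6 days under puromycin. UHRF1 binds hemimethylated DNA and the tail of histone H3 and is required to maintain DNA methylation. The design asked which transcripts depend on it. Each array gave a log2 value for 54613 probe sets, and the array medians were 3.002 for the control, 2.977 for hairpin 2 and 3.044 for hairpin 5. Across probe sets, Pearson's r was 0.989 between the control and hairpin 2, 0.989 between the control and hairpin 5 and 0.987 between the hairpins. The small number of arrays limits the precision. Differences below are hairpin minus control on the log2 scale unless another contrast is named, and a pair of values gives hairpin 2 first and hairpin 5 second.

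UHRF1 transcript was lower with both hairpins. Its only probe set (225655_at) read 8.54 on the control array, 6.20 with hairpin 2 and 6.67 with hairpin 5, which was 5.09-fold lower with hairpin 2 and 3.68-fold lower with hairpin 5. The mean difference was −2.11 ± 0.33 (SD, n = 2 hairpins). UHRF1 passed limma's test when adjusted over the list alone of DNA methylation machinery (adjusted p = 0.0132) and did not when adjusted over all genes (adjusted p = 0.999). Adjustment over a list alone, here and below, makes no correction for the number of lists. UHRF2, the paralog of UHRF1, differed by −0.08 and −0.92. DNMT1, the maintenance DNA methyltransferase, differed by 0.12 and −0.31, and the de novo enzymes by 0.00 and −0.11 for DNMT3A and by 0.11 and −0.21 for DNMT3B. EHMT1, an H3K9 methyltransferase, was lower on both arrays (−0.49 and −0.89), although the mean over its probe sets was −0.09. Of the 21 tested genes of the DNA methylation list, 7 were lower and 4 higher with both hairpins, the latter led by CTCF (0.50 and 0.36), and the list as a whole did not pass camera (adjusted p = 0.305). The cell cycle inhibitor CDKN1A differed by −0.77 and 0.37. CDKN2A, another such inhibitor, was 0.49 higher with hairpin 2 and level with the control with hairpin 5, and its mean difference was 0.02 as the mean over its probe sets and turned to −0.32 when probe sets whose name ends in _x_at were left out.

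**Figure D1:**
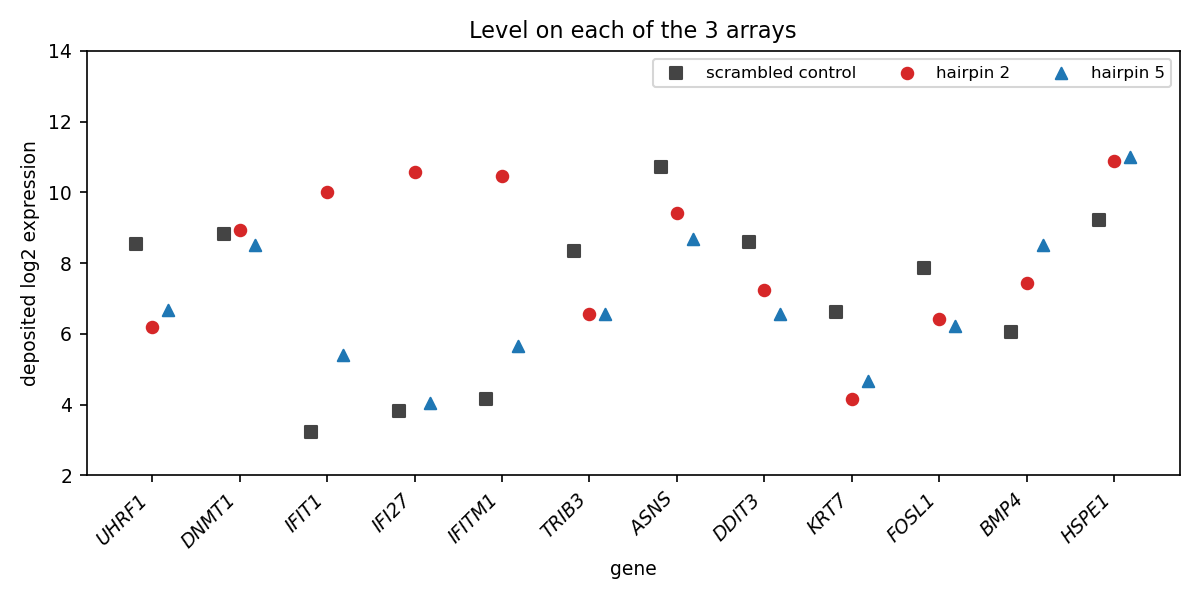
Deposited log2 expression (vertical axis) of UHRF1 and of genes named in the text on the control, hairpin 2 and hairpin 5 arrays, 1 point per array. UHRF1 stood at 8.54 on the control array against 6.20 and 6.67 with the hairpins, while IFITM1 stood at 10.46 with hairpin 2 against 4.15 on the control array and 5.66 with hairpin 5.

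Among 11865 genes tested, 12 were at least 2-fold higher than the control with both hairpins. HSPE1, the mitochondrial co-chaperonin, was 1.67 and 1.78 higher, and the efflux transporter ABCC2 was 1.77 and 1.61 higher. BMP4, a secreted ligand of the TGF-beta family, was 1.37 and 2.46 higher. RNF43, a ubiquitin ligase that removes Wnt receptors from the cell surface, was 1.01 and 1.06 higher. SMARCA1, an ISWI chromatin remodelling ATPase, was 1.22 and 1.02 higher, ENC1 1.58 and 1.99, CYB5B 1.48 and 1.18, and SUSD2 1.25 and 1.05. EPB41L4B was 2.75-fold and 2.82-fold higher. The interferon-inducible genes IFIT1 (6.79 and 2.19) and IFITM1 (6.31 and 1.51), and the keratin KRT23 (3.53 and 1.28), completed this group with far larger values for hairpin 2.

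On the other side, 33 genes were at least 2-fold lower with both hairpins, UHRF1 among them. The keratin KRT7 differed by −2.46 and −1.96, and CSTA, a cysteine protease inhibitor of epithelia, by −1.85 and −2.51. The pseudokinase TRIB3 differed by −1.78 and −1.76, the transcription factor DDIT3 by −1.37 and −2.04, and asparagine synthetase, ASNS, by −1.29 and −2.04. FOSL1, a subunit of the AP-1 transcription factor, differed by −1.44 and −1.63, and the GTPase RAC3 by −1.64 and −1.26. Ranked by the smaller of the 2 hairpin differences, the others at the top were TAF15 (−2.19 and −1.49), TUBE1 (−1.51 and −2.06), NAV3 (−1.41 and −1.27) and DNAH14 (−1.33 and −1.41).

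No gene passed limma at an adjusted p of 0.05 over all genes, and the lowest adjusted p was 0.999. At an unadjusted p under 0.05 there were 277 genes, 91 higher and 186 lower, where 593 would come by chance. With an intensity trend in the variance prior, limma called 1 gene, HSPE1 (adjusted p = 0.0475), and with a robust prior it called 0. In simulated arrays of the same size, the test recovered 0% of 200 genes changed by 1 on the log2 scale, 76.0% of those changed by 2 and 90.5% of those changed by 3. It also called 5, 22 and 16 unchanged genes in these runs, so its calls held more false ones than the threshold allows for. Simulated unchanged arrays sharing 1 control gave on average 39.95 genes at least 2-fold higher with both hairpins (range 28 to 54) and 40.31 lower (range 25 to 58). The noise in that simulation was taken from the hairpins' differences from each other, effects particular to 1 hairpin included. The observed 12 lay below the simulated range and the observed 33 inside it, while independent lists would overlap in 0.346 and 1.32 genes. Part of any overlap may come from the single control array, which could not be split. Several sizes rested on the brightest probe set: as the mean over a gene's probe sets, KRT7 stood at −0.59, TAF15 at −0.47, TUBE1 at −0.88, ASNS at −0.92, TRIB3 at −1.15, ENC1 at 0.88, SUSD2 at 0.77, EPB41L4B at 0.27 and SMARCA1 at 0.40. NAV3 and DNAH14 then lay under the tested level. With both hairpins, 9 genes rather than 12 were then 2-fold higher and 13 rather than 33 lower.

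**Figure D2:**
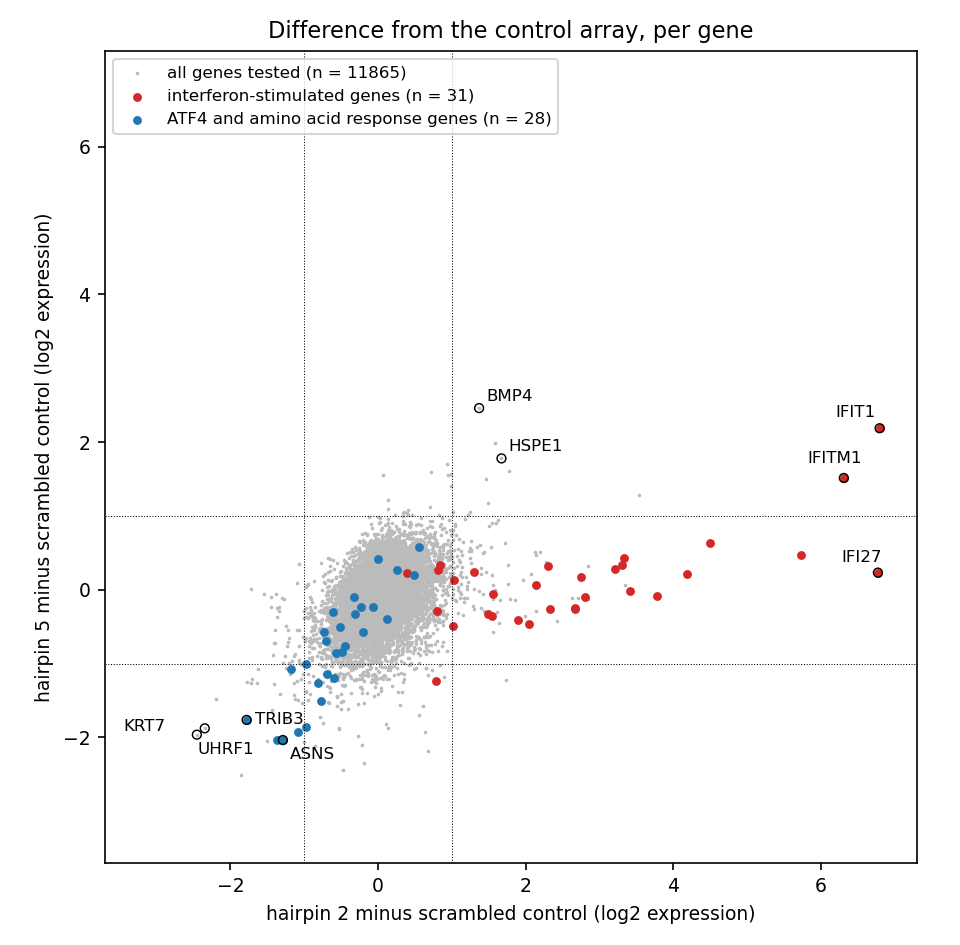
Difference from the control array on the log2 scale for hairpin 2 (horizontal axis) and hairpin 5 (vertical axis), 1 point per gene over 11865 genes, with dotted lines at 2-fold. Of these genes, 12 lay at least 2-fold up and 33 at least 2-fold down on both axes, and the interferon-stimulated genes spread along the hairpin 2 axis.

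Genes of the amino acid response driven by the transcription factor ATF4 were lower with both hairpins. Of the 28 tested genes of this list, 23 were lower with both hairpins, 3 higher and 2 mixed, and the median difference was −0.58 with hairpin 2 and −0.73 with hairpin 5. They included enzymes of serine and asparagine synthesis, among them PSAT1 (−1.18 and −1.08) and ASNS, the transcription factors DDIT3 and CEBPG (−1.09 and −1.93), TRIB3, and the secreted glycoprotein STC2 (mean of the hairpins −0.99). The list shifted lower in camera with its preset correlation (adjusted p = 2.59e-13), and had adjusted p = 0.893 with an estimated correlation. That estimate rests on 1 residual degree of freedom per gene. Most lists, called or not, then had the same adjusted p, so this alternative decides nothing here or for the lists below. The p-values at the preset correlation, here and below, take genes as their units. They hold no spread between cultures and describe these arrays only. Both medians lay below those of all 10000 random lists matched on expression (percentile 0). Over all genes 0 members passed limma, and 6 did when adjusted over the list alone: TRIB3, DDIT3, ASNS, CEBPG, PSAT1 and STC2. PSAT1 and STC2 fell outside the rule for named genes and were picked after their values were seen, as were the members NUPR1 (0.55 and 0.58), CTH (0.48 and 0.19) and CBS (0.26 and 0.27), which were higher with both hairpins. Averaged over probe sets and hairpins, ASNS stood at −0.92, TRIB3 at −1.15, PSAT1 at −0.77, CEBPG at −1.17, STC2 at −1.05, CTH at 0.17 and CBS at 0.12. ATF4 itself differed by −0.32 and −0.32 and was also named after its value was seen.

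Unfolded protein response genes shifted lower in camera with its preset correlation (adjusted p = 6.76e-04, and 0.893 with an estimated correlation). Of 21 tested, 13 were lower with both hairpins, 2 higher and 6 mixed, with medians of −0.16 and −0.49. HSPA5, the main chaperone of the endoplasmic reticulum, differed by −0.61 and −0.55, its co-chaperone HYOU1 by −0.39 and −0.45, the membrane-bound factor CREB3L2 by −0.79 and −0.76, and the sensor ATF6 by −1.63 and −1.07. No member passed limma over all genes or adjusted over the list alone. As means over their probe sets, ATF6 stood at −0.40 and CREB3L2 at −0.20.

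Immediate early and AP-1 genes had medians of −0.08 and −0.26, and 14 of 28 were lower with both hairpins, 6 higher and 8 mixed. Beside FOSL1, the lowest were the transcription factor KLF4 (−0.79 and −1.73), the phosphatase DUSP5 (−0.79 and −0.72) and ZFP36, which promotes mRNA decay (−0.51 and −0.84). As a mean over its probe sets, with the hairpins averaged, KLF4 stood at −0.74. The list shifted lower in camera (adjusted p = 0.0198), with adjusted p = 0.893 with an estimated correlation. FOSL1 was the 1 member that passed limma when adjusted over the list alone, and 0 passed over all genes. The call ended in camera on ranks (adjusted p = 0.0687) and with the mean of each gene's probe sets (adjusted p = 0.125).

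Interferon-stimulated genes were much higher with hairpin 2. Of 46 on the array, 31 were tested, and 26 of these were at least 2-fold higher than the control with hairpin 2. With hairpin 5, 2 were at least 2-fold higher, IFIT1 and IFITM1, and 1 lower, ISG20 (0.79 and −1.24). As the mean over its probe sets ISG20 was 0.91 and −0.91. The filter used the mean over all arrays. Members such as IFIT3 (2.83 on the control array, 3.05 with hairpin 5) and OAS1 (2.71 and 3.05) passed it only through hairpin 2. This raises the share, the list median and its percentile with hairpin 2, and may also strengthen the camera call on the list. Over all 46 on the array, with no filter on expression, that call held with a larger adjusted p. Camera tested the mean of the hairpins, so hairpin 2 could carry the call. The list median was 2.32 with hairpin 2 and 0.13 with hairpin 5, at percentiles 100 and 99.5 of random lists. IFIT1, which binds RNA lacking the host cap structure, was 111-fold higher with hairpin 2 and 4.55-fold higher with hairpin 5. IFITM1, a membrane protein that restricts virus entry, was 79.2-fold and 2.85-fold higher. IFI6 was 5.73 and 0.46 higher on the log2 scale, and BST2, which tethers budding virus, 4.50 and 0.63. Of all members, 17 were higher with both hairpins and 14 were mixed. The list shifted higher in camera (adjusted p = 6.09e-11), with adjusted p = 0.893 with an estimated correlation. No member passed limma over all genes or adjusted over the list alone, and the SD between hairpins was 3.26 for IFIT1 and 3.39 for IFITM1.

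Between the hairpins, 376 genes differed at least 2-fold, 352 higher with hairpin 2 and 24 higher with hairpin 5. The 5 genes furthest above hairpin 5 with hairpin 2 were all interferon-stimulated: IFI27 (6.54 higher), IFI6 (5.27), IFITM1 (4.80), IFIT1 (4.61) and IFIT3 (3.97). In the other direction stood AMOTL2, a scaffold of the Hippo pathway (hairpin 2 minus hairpin 5, −1.74), the translation termination factor ETF1 (−1.50), the transcriptional regulator ARID5B (−1.49), TTC5 (−1.42) and PDGFRL (−1.36). Against the control with hairpin 2, AMOTL2 stood at −1.73, ETF1 at −1.55 and PDGFRL at −1.45, while ARID5B was 1.56 higher with hairpin 5. Against the control, hairpin 2 had 137 genes at least 2-fold higher and 68 lower, and hairpin 5 had 30 higher and 230 lower. ANXA10, an annexin, was the 1 gene at least 2-fold higher with hairpin 2 (1.73) and 2-fold lower with hairpin 5 (−1.22). With 1 array per hairpin these differences have no replicate check, and the count between hairpins was 175 with the mean of each gene's probe sets. On that basis hairpin 2 minus hairpin 5 was 2.49 for IFIT3, −0.63 for ETF1 and −0.59 for TTC5, ETF1 stood at −0.83 against the control with hairpin 2, and ARID5B lay under the tested level.

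Across the 11865 genes, which are not independent replicates, the differences of the hairpins from the shared control correlated with Pearson's r of 0.383 and Spearman's rho of 0.367. Simulated unchanged arrays with a shared control gave r of 0.498 (range 0.461 to 0.540) and rho of 0.474. The covariance was 0.0590 against 0.0902 in the simulation, a difference of −0.0312. The simulated noise also holds effects particular to 1 hairpin, which raise the simulated covariance. The difference therefore cannot tell whether there was a shared effect.

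Lists of genes often silenced by DNA methylation did not pass camera, nor did the Polycomb and H3K9 methylation machinery. The filter dropped members with a low mean over the arrays, so these tests say little about genes that stayed near background. Of 35 cancer-testis and germline genes on the array, 6 were expressed at the tested level, with medians of 0.17 and 0.12 (adjusted p = 0.406). The cancer-testis antigen MAGEB2 was 0.32 and 0.44 higher, and MAGEA1 was 0.89 and 0.17 higher. Of 44 genes on the array reported as promoter-methylated in colorectal cancer, 20 were tested. They had medians of 0.02 and 0.02 (adjusted p = 0.496), and 7 were higher and 6 lower with both hairpins. The proteoglycan gene SPOCK2 was 0.49 and 0.62 higher and NDRG4 0.66 and 0.47 higher, while NKD2, a Wnt pathway inhibitor, differed by −0.37 and −0.48 and the repair gene MGMT by −0.11 and −0.30. Imprinted genes had medians of 0.01 and −0.22 (adjusted p = 0.496), 5 lower and 3 higher with both hairpins, with GRB10 at −0.72 and −0.59 and NNAT at 0.11 and 0.26. Polycomb and H3K9 methylation genes had medians of 0.08 and −0.04 (adjusted p = 0.879), 10 higher and 11 lower with both hairpins, with SUZ12 at 0.64 and 0.42 and PHC3 at −0.64 and −0.93. Averaged over probe sets and hairpins, GRB10 stood at −0.31, SUZ12 at 0.14 and PHC3 at −0.15.

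Proliferation and DNA damage lists did not pass camera either. S phase genes had medians of 0.10 and −0.04 (adjusted p = 0.620), 16 higher and 15 lower with both hairpins. SLBP, the histone mRNA binding protein, was 0.71 and 0.71 higher and cyclin gene CCNE1 0.59 and 0.54 higher, while E2F8 differed by −0.50 and −0.52. G2 and mitosis genes had medians of −0.02 and −0.09 (adjusted p = 0.477), 20 lower and 11 higher with both hairpins, with the kinesin KIF14 1.63-fold and 2.01-fold lower and CDCA8 0.48 and 0.32 higher. Homologous recombination genes had medians of −0.01 and −0.14 (adjusted p = 0.629), 9 lower and 5 higher, with FANCG at −0.46 and −0.45 and EXO1 at 0.42 and 0.24. Targets of p53, which is wild type in HCT116, had medians of 0.12 and 0.06 (adjusted p = 0.620), and 15 were higher and 9 lower with both hairpins. Among them SERPINB5 was 0.95 and 0.53 higher and XPC 0.33 and 0.45 higher, while GADD45A differed by −0.69 and −0.93 and GDF15 by −0.97 and −0.37. Apoptosis regulators had medians of −0.06 and −0.11 (adjusted p = 0.439), 14 lower and 6 higher, with PMAIP1 at −0.55 and −0.68 and BOK at 0.55 and 0.34. Senescence-linked secreted factors had medians of −0.13 and −0.21 (adjusted p = 0.238), 6 lower and 3 higher, with the urokinase gene PLAU at −1.71 and −1.22, its receptor PLAUR at −0.66 and −1.53, and IGFBP2 at 0.51 and 0.45. The 6 tested histone genes had medians of 0.62 and −0.04 (adjusted p = 0.123), and H2AC6 was 2.07 and 0.21 higher. The averages over probe sets and hairpins put CCNE1 at 0.32, SERPINB5 at 0.43, GDF15 at −0.23, PMAIP1 at −0.34 and PLAUR at −0.72, and GDF15 turned to 0.08 without probe sets named _x_at.

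Among metabolic lists, glycolysis and hypoxia genes had medians of 0.18 and 0.02 (adjusted p = 0.0833, and 0.0485 after cyclic loess), and 16 were higher and 8 lower with both hairpins. The glucose transporter SLC2A1 was 0.71 and 1.12 higher and ALDOC 0.67 and 0.64 higher, while DDIT4 differed by −0.57 and −0.86 and the angiogenic factor VEGFA by −0.51 and −1.04. Oxidative phosphorylation genes had medians of −0.12 and −0.08 (adjusted p = 0.327), 20 lower and 6 higher, with CYC1 at −0.25 and −0.41 and ATP5F1B at 0.15 and 0.40. Ribosomal protein genes had medians of −0.10 and −0.11 (adjusted p = 0.288), and 28 of 32 were lower with both hairpins. Metallothionein and NRF2 target genes had medians of −0.12 and −0.29 (adjusted p = 0.123), 15 lower and 4 higher, with the cystine transporter SLC7A11 at −0.78 and −1.51 and HMOX1 at 0.69 and 0.66. Cholesterol synthesis genes had medians of −0.06 and 0.00 (adjusted p = 0.814), 8 lower and 6 higher, with DHCR7 at −0.38 and −0.33 and TM7SF2 at 0.42 and 0.70. With probe sets and hairpins averaged, SLC2A1 stood at 0.43, VEGFA at −0.12 and SLC7A11 at −0.75.

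Wnt target genes had medians of −0.06 and 0.27 (adjusted p = 0.238), with BMP4, RNF43 and ZNRF3 (0.76 and 0.73), a second ligase of Wnt receptors, at the top of 5 higher with both hairpins, and NKD2 first of 6 lower. Epithelial junction and keratin genes had medians of 0.05 and −0.10 (adjusted p = 0.911), 10 lower and 7 higher with both hairpins, and KRT7 alone passed limma when adjusted over the list alone (adjusted p = 0.0128). Enterocyte and goblet genes had medians of −0.07 and 0.06 (adjusted p = 0.727), 6 higher and 4 lower, with CA2 at −0.21 and −0.78 and CDX2 at 0.35 and 0.43. Mesenchymal and TGF-beta genes had medians of 0.05 and 0.04 (adjusted p = 0.233), 7 higher and 3 lower, with VIM 0.59 and 0.39 higher and TWIST1 at −0.24 and −0.41. Antigen presentation genes had medians of 0.17 and −0.18 (adjusted p = 0.727), 4 higher and 3 lower, with CIITA 0.48 and 0.25 higher and CD74 at −0.37 and −0.31. NF-kB and inflammatory genes had medians of 0.01 and 0.21 (adjusted p = 0.824), and 5 were higher and 3 lower with both hairpins. NFKBIA was 0.27 and 0.31 higher, while CXCL8 differed by −0.40 and −0.77, LIF by −0.66 and −0.38 and SOD2 by −0.36 and −0.74. As means over their probe sets, with the hairpins averaged, VIM stood at 0.17, NFKBIA at 0.18, KRT7 at −0.59, CDX2 at 0.09 and CD74 at −0.20, and CIITA and CXCL8 lay under the tested level. The median of the hairpins' mean difference and the direction of the test had opposite signs for the promoter-methylated, enterocyte, epithelial, cholesterol and Polycomb lists, and the mean and the test did for the NF-kB list.

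Markers of other cell types were also compared. The 8 tested fibroblast and endothelial markers had medians of 0.21 and 0.41 and shifted higher in camera (adjusted p = 0.0198, and 0.893 with an estimated correlation), with PDGFRB at 3.49 on the control array and 0.33 and 0.43 higher. The 9 tested neuronal markers had medians of 0.15 and 0.41 and also shifted higher (adjusted p = 0.0382, and 0.893 with an estimated correlation), led by the tubulin TUBB3, 0.92 and 0.78 higher from 9.29. No member passed limma over all genes or adjusted over the list alone. Both calls ended with no filter on expression (adjusted p = 0.0556 and 0.139) and with the mean of probe sets (adjusted p = 0.0509 and 0.128), and the neuronal call also without probe sets named _x_at (adjusted p = 0.138). The 5 tested leukocyte markers had medians of 0.30 and 0.21 (adjusted p = 0.123), with CORO1A 1.39 and 0.21 higher.

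**Figure D3:**
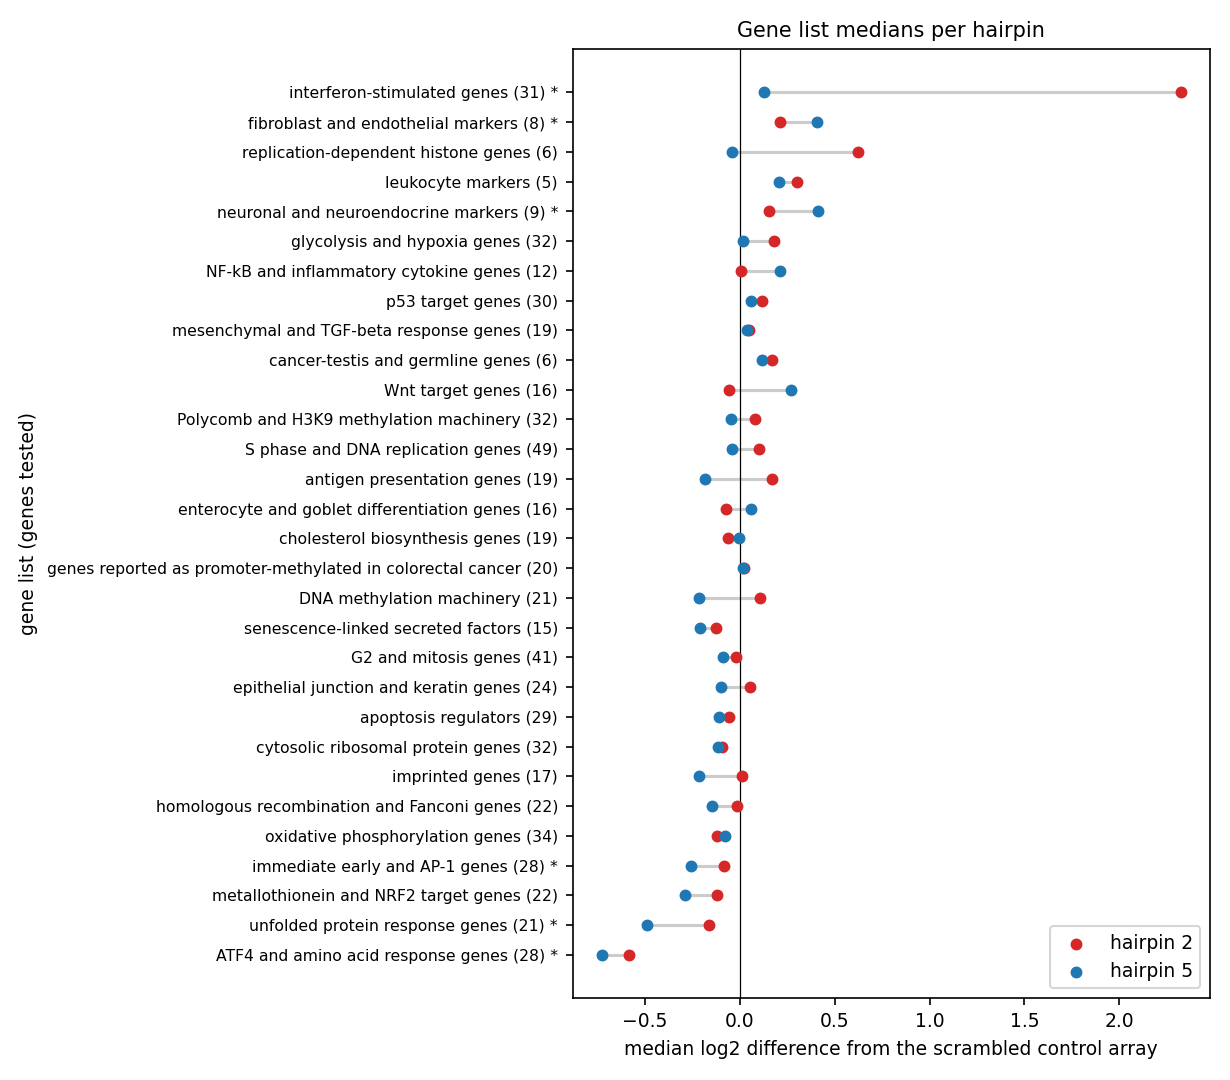
Median difference from the control array on the log2 scale (horizontal axis) for each of 30 gene lists, with separate points for hairpin 2 and hairpin 5; an asterisk marks lists with a camera adjusted p under 0.05 at the preset correlation. The interferon-stimulated list stood at 2.32 with hairpin 2 and 0.13 with hairpin 5, and the ATF4 list at −0.58 and −0.73.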

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

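The tests of explanations in this part were chosen after the results were seen, apart from the leukocyte test.

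Probe sets outside the gene comparisons also differed from the control. Among 3250 probe sets at the tested level with no single gene name, 3 were at least 2-fold higher than the control array with both hairpins: 201120_s_at (1.52 and 1.42), 208750_s_at (1.15 and 1.13, matching several genes) and 230748_at (2.33 and 1.01). Another 4 were at least 2-fold lower. Which transcripts they measure was not determined.

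Interferon-stimulated genes were higher with hairpin 2 than with hairpin 5, although the hairpins lowered UHRF1 by similar amounts. On these arrays the ratio of list medians, hairpin 5 over hairpin 2, was 0.0564 (bootstrap 95% interval over genes −0.0930 to 0.113), where the ratio for UHRF1 was 0.800, but a response in proportion to UHRF1 loss stays open because that interval holds no spread between cultures. Leukocyte RNA in the hairpin 2 sample was not excluded by the marker values, although the samples are a carcinoma cell line and their labels name no leukocytes. The median over 23 leukocyte genes, hairpin 2 minus the mean of the other arrays, was −0.074 (−0.18 to 0.07). Only 5 of them were at the tested level, so the bound set beforehand rested mostly on genes near the floor. Among those 5, the median of hairpin 2 minus hairpin 5 was −0.022, CD79B was alike with both hairpins (0.52 and 0.55), and only CORO1A was 2-fold higher with hairpin 2 (1.39). Outside that list, the lymphocyte gene PRF1, picked after its value was seen, was 3.35 and 0.07 above the control. An innate response to hairpin 2 itself may remain, as 2 members were 2-fold higher with hairpin 5 against 26 with hairpin 2, and with 1 array per hairpin these cannot be told apart.

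The ATF4 and amino acid response genes were lower with both hairpins. An intensity trend or scaling between arrays is argued against as the whole cause, since the list median was −0.63 after cyclic loess (bootstrap 95% interval over genes −0.92 to −0.36). Genes are not independent, so that interval describes these arrays and holds no spread between cultures. The state of the single control array, such as a culture with more amino acid stress, could give the same list median of −0.66. It cannot be told apart from an effect of UHRF1 loss, because there is 1 control array.

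Genes 2-fold from the control with hairpin 5 were mostly lower. A scale difference between arrays is argued against as the whole cause, since 82.9% were lower after cyclic loess (exact 95% interval 77.4 to 87.5), against 88.5% before. The intervals in this paragraph are over genes, which are not independent. They describe these arrays and hold no spread between cultures. Noise of the brightest probe set is argued against only as the whole cause. For 105 of the 230 lower genes, the other expressed probe sets had a median difference of −0.48 (−0.63 to −0.36). That is smaller than the 2-fold by which the genes were chosen, so part of the size may be such noise. An effect of hairpin 5 apart from UHRF1 stays open: with hairpin 2 the median of the 230 lower genes was −0.36 (−0.46 to −0.28), but these genes were chosen against the control array that hairpin 2 shares, and genes chosen so in simulated unchanged arrays had medians from −0.77 to −0.47. With 1 array per hairpin it cannot be told apart from a difference between single cultures.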

How the results depend on the processing

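The values without the interferon list were chosen after the results were seen. UHRF1 kept its direction under every alternative run, which its 1 probe set and its same sign with both hairpins largely fixed in advance. No gene passed the adjusted p in either direction under any alternative except an intensity trend in the prior, which called 1 gene, HSPE1, and 197 to 881 features had an unadjusted p under 0.05. The correlation between hairpins was 0.364 with no filter on expression, 0.431 with the stricter filter, 0.401 after cyclic loess and 0.400 without the interferon list. Lists shifted higher numbered 1 with no filter, 1 with the stricter filter, under which fewer members were tested, and 1 with the mean of probe sets, against 3. With the mean of probe sets, 13 genes were 2-fold lower with both hairpins and 175 differed 2-fold between hairpins. At 1.5-fold, 90 genes were higher and 189 lower with both hairpins, and at 3-fold 3 were higher and 4 lower, by construction. Simulated unchanged arrays gave 223 to 295 higher and 211 to 300 lower at 1.5-fold, so both observed counts lay below the simulated ranges. The simulated noise also holds effects particular to 1 hairpin, which raise the simulated counts, so this does not show that a shared effect was absent. Leaving out a hairpin left 30 to 137 genes 2-fold higher and 68 to 230 lower, with no test. Camera with an estimated correlation called 0 lists higher and 0 lower. That estimate rests on 1 residual degree of freedom per gene, and most lists, called or not, had the same adjusted p, so it decides nothing about them. Where no construction is named, the cause was not tested. Of 1430 recomputed values of 186 named genes, 1403 kept their direction and 27 took the other, 18 of them from leaving out a hairpin. Many of these values could not turn. The filters leave a gene's difference unchanged, as does probe-set handling for a gene with 1 probe set. Genes named for the same sign with both hairpins cannot turn when a hairpin is left out. The mean of probe sets turned PDIA3 (−0.29), CALR (−0.10), IGF2R (0.06), ISG20 (0.00), HSPD1 (0.01) and EGR1 (0.12), and leaving out _x_at probe sets turned CALR (−0.13), CDKN2A (−0.32) and GDF15 (0.08), none of them called. No paired analysis was possible because there is only 1 control array. Signal over background limits low genes, since no detection calls were used.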

Other observations

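The genes in this part were named after their values were seen.

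With hairpin 2, 83 genes were at least 2-fold higher than on both other arrays, 25 of them on the interferon list and 58 not. The list was written from general knowledge and is not complete, so the 58 were not shown to be a response apart from interferon. Outside the list were PRF1, the pore-forming protein of cytotoxic lymphocytes (3.35 above the control), the intestinal keratin KRT20 (2.85), the water and glycerol channel AQP3 (2.84), the nuclear body protein SP110 (2.70), DTX3L, the partner of PARP9 (2.63), the linker histone gene H1-2 (2.14) and EIF2AK2, the double-stranded RNA sensing kinase PKR (1.85). With hairpin 5 the same genes differed from the control by 0.07 for PRF1, −0.13 for KRT20, 0.32 for AQP3, −0.12 for SP110, −0.12 for DTX3L, −0.29 for H1-2 and −0.15 for EIF2AK2. As means over their probe sets, AQP3 was 1.54 and EIF2AK2 0.91 above the control with hairpin 2.

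With hairpin 5, 92 genes were at least 2-fold lower than on both other arrays and 3 higher. NT5E, the ecto-enzyme CD73 that makes adenosine, differed by −2.44 from the control with hairpin 5 and by −0.48 with hairpin 2. SRD5A1, steroid 5-alpha reductase, differed by −2.10 and −0.22, and the glucocorticoid-induced gene TSC22D3 by −1.87 and 0.14. As means over their probe sets with hairpin 5, NT5E stood at −1.50, SRD5A1 at −1.11 and TSC22D3 at −0.56. Set apart in the same way, the control array had 45 genes, 33 higher and 12 lower than on both hairpin arrays, fewer than the 96 of hairpin 2 or the 95 of hairpin 5.

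HSPE1, which limma called with an intensity trend in the prior, was 1.67 and 1.78 higher with the hairpins, while HSPD1, its partner chaperonin encoded from the same bidirectional promoter, differed by −0.23 and 0.09. The immediate early genes EGR1 and KLF2 went opposite ways between hairpins, at 0.89 and 0.84 with hairpin 2 and −1.18 and −1.03 with hairpin 5, although KLF2 was 0.53 and −0.53 as the mean over its probe sets.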
